A study of Mus musculus with 15 samples.

How the data were processed

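Gene expression was measured on 15 Affymetrix mouse arrays in 5 groups of 3. Cells were sorted by flow cytometry into side population (SP) cells, which are defined by low retention of a DNA dye that ABC transporters pump out, and non-side population (non-SP) cells. The tumour groups came from tumorspheres, free-floating cultures grown from mouse brain tumours, of lines 3447 and 4346. Line 3447 gave an SP and a non-SP group and line 4346 gave an SP group. The control groups were SP and non-SP cells of untransformed neurospheres, the corresponding cultures of neural stem and progenitor cells. Per the labels, total RNA was isolated with a small-scale column kit, amplified with a NuGEN Ovation Pico kit and labelled with biotin.

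The deposited values are intensities, MAS5 signals on a linear scale that the authors computed in Affymetrix Expression Console, whose version is not given in the sources used here. The mean signal without the lowest and highest 2% of probe sets was 500 on each of the 15 arrays, so each array had been scaled to a common mean. Of 45101 probe sets, 64 were controls and were left out of the tests. Among the remaining 45037, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none. Gene symbols and Entrez identifiers were taken from the deposited array annotation, and 34741 probe sets matched a mouse RefSeq gene by Entrez identifier, with 0 symbols changed. The RefSeq annotation of assembly GRCm38.p6 served only for the chromosome of each gene and for the order of genes.

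The rule fixed in advance was to normalize between arrays only if the highest array median exceeded the lowest by over 1.5 times. The medians ran from 40.0 to 89.3, a ratio of 2.23, so quantile normalization was applied and then log2 of the value plus 16. Probe sets were kept when they lay above the median of their own array in at least 3 arrays, which left 26256. Each gene was represented by its probe set with the highest mean, which gave 11908 genes tested of 18193 annotated. Among genes named for their fold change, 62 results had other probe sets. In 0 of them did one move the opposite way, but some moved by far less. Signals of each gene are quoted as deposited, and fold changes are on the normalized log2 scale with the added 16, which understates the change of genes with a low signal. Values are given as mean ± SD of the deposited signal (n = 3 arrays per group) and as log2 fold change ± SE. For arrays, the number of arrays limits the precision.

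Differences were tested with limma 3.58.1 in R 4.3.3, as a linear model of all 15 arrays with 5 group means, 10 residual degrees of freedom, a trend of spread on level, two-sided moderated tests and Benjamini-Hochberg adjustment over the 11908 genes at 0.05. There were 9 comparisons: SP against non-SP in line 3447 and in neurospheres, the difference of these effects and their average; the SP of each line and of both lines against the neurosphere SP; the non-SP of line 3447 against the neurosphere non-SP; and the SP of line 3447 against that of line 4346. The design, the alternatives and the gene lists were fixed before the data were examined, except where a passage says otherwise.

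Genes were named by a fixed rule. It took genes past the threshold whose sides did not overlap in any array, namely the 10 with the highest and the 10 with the lowest fold change in the SP against non-SP comparisons and in those of each tumour line's SP with the neurosphere SP, and 6 of each in the others, where the interaction and the averaged comparison needed no separation. Where no gene passed, the 5 with the smallest p were named. Abcg2, Abcb1b, Egfr, Nes, Prom1 and Sox2 were added in every comparison, and so were up to 4 members of each gene list with the smallest p. Predicted genes and clone names were counted and not named. A pair of genes that the rule also named, Abcb1a and Trp53, was not among the genes tested.

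Gene lists for cell types, pathways and stress responses were written in advance with 785 entries, of which 723 had a probe set and 593 were tested, and 21 genes stood on more than 1 list. Of the lists, 30 were tested in each comparison and 1 had fewer than 3 measured genes. They were tested with the camera function of limma with a preset correlation of 0.01 between genes, again with a correlation estimated from the data, and with the fry function, which tests whether the genes of a list move one way. Adjustment was over the lists of each comparison. Of 270 list tests, 75 passed with the preset correlation and 4 with the estimated one; where the text gives a list's call, the adjusted p with the preset correlation comes first.

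Whether equal replicate numbers pair SP and non-SP arrays was checked from the correlation of their deviations from the group means. The study description takes the neurospheres from 3 independent mice in a passage and from mice injected with neurospheres in another, so their origin is not certain. In neurospheres the correlations of equally numbered arrays were 0.577, 0.522 and 0.621, above the limit of 0.1, so these arrays were treated as pairs in the blocked alternatives. In line 3447 they were -0.225, -0.249 and -0.120, so a block by equal numbers has no basis in the data there. Other pairs of 3447 arrays did exceed the limit: SP array 1 with non-SP array 2 (0.366), 2 with 3 (0.296) and 3 with 1 (0.217). Whether these arrays belong together in that order is not given in the labels, and no block was built on it. Shared control arrays, and paired ones in the comparison of the SP and non-SP contrasts, were allowed for with 20 simulated sets of unchanged groups each. The pipeline was tested on simulated data, in which 200 of 11908 genes were changed. For SP against non-SP in line 3447 it recovered 44.8% of genes changed by a log2 of 1, 83.6% by 2 and 95.5% by 4. For SP against non-SP in neurospheres it recovered 23.9%, 76.1% and 95.5%, and for the SP of line 3447 against the neurosphere SP 29.9%, 83.6% and 98.5%. For the SP of both tumour lines against the neurosphere SP it recovered 41.8%, 89.6% and 97.0%, and for the SP of line 3447 against that of line 4346 40.3%, 91.0% and 95.5%. In the same order, 7 of 156, 7 of 137, 3 of 144, 14 of 166 and 12 of 163 calls were false. Each comparison was simulated once with the same spread per gene. Differences in recovery between comparisons of 3 arrays with 3 thus reflect the draw and not their power. A simulated list shift was recovered, and 0 of 30 unshifted lists were called. Simulated genes were drawn independently, so this does not test the preset correlation on lists whose genes move together. The estimated correlation was 0.503 for the G1/S list, 0.692 for G2/M and 0.731 for cholesterol synthesis.

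Alternatives covered the added constant (1 and 64), the scaling between arrays, the filter, the summary of several probe sets, the arrays in the fit, the trend of spread, array weights, a replicate block, the threshold, the list correlation and leaving out each array in turn. Chosen after the data were seen were the removal of 2 arrays of doubtful quality together and a replicate block for neurospheres alone. Detection calls, scan dates and image files were not used here.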

Results

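The arrays covered side population and non-side population cells of brain tumour line 3447, side population cells of line 4346, and side population and non-side population cells of untransformed neurospheres, with 3 arrays in each of the 5 groups. Median signals per array lay between 40.0 and 89.3. The first principal component held 51.0% of the variance and separated all 9 tumour arrays from all 6 neurosphere arrays, and the second held 13.3%. A pair of arrays stood apart from the rest. Array 3 of the 3447 SP had the highest median, 89.3, and the lowest mean rank correlation with its own group, 0.855. Array 3 of the 4346 SP had a ratio of 3' to 5' signal of 5.30 for actin, against 2.49 to 3.29 on the other arrays, and of 2.00 for Gapdh, against 1.33 to 1.62.

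The comparison of SP with non-SP cells of line 3447 asked which genes mark the dye-excluding cells of the tumour. Smad7, an inhibitor of TGF-beta signalling, was higher in SP cells, with a signal of 505 ± 117 against 79.1 ± 34.0 (SD, n = 3). Its log2 fold change was 2.37 ± 0.32 (SE) with an adjusted p of 0.0169, and the arrays of the groups did not overlap. Abcg2, the dye-exporting transporter by which side populations are commonly recognised, had a signal of 3219 ± 994 in SP and 1717 ± 395 in non-SP cells. The log2 difference of Abcg2, 0.90 ± 0.23, did not pass (adjusted p = 0.266). Of the stem cell genes, Nes, Sox2 and Prom1 had log2 differences of -0.40 ± 0.24, 0.16 ± 0.12 and -0.94 ± 0.71 and did not pass, with adjusted p of 0.782, 0.832 and 0.846. Of 11908 genes, 1 was higher and 0 lower, and 859 had an unadjusted p under 0.05; with the compared groups alone 17 were higher and 1 lower, and with array weights 48 and 2. In 17.5% of genes the groups did not overlap, against 10% by chance. The Smad7 call was lost when array 1, 2 or 3 of the 3447 SP (adjusted p = 0.111, 0.102 and 0.0715) or array 2 or 3 of the 3447 non-SP (0.116 and 0.147) was left out. It was also lost with arrays centred on their medians (adjusted p = 0.0648), without a filter (adjusted p = 0.0520) and with the mean of the probe sets of the gene (adjusted p = 0.139). The count was then 0 without 3447 SP array 2 or 3 or non-SP array 2 or 3, and it was 3 without non-SP array 1. It was 4 and 2 without 4346 SP arrays 1 and 3, and 2 and 3 without neurosphere non-SP arrays 1 and 2.

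Gene lists moved in line 3447 SP cells where single genes mostly did not pass. DNA replication and G1/S genes were lower as a group, with 29 of 30 measured members below 0 and a median log2 of -0.65. For the G1/S list the adjusted p was 4.84e-17 (adjusted p = 0.219 with an estimated correlation). Among the replication genes the helicase subunit Mcm6 was at -0.88 ± 0.21 and the replication clamp Pcna at -0.48 ± 0.16; 0 members passed over all genes and 1 was lower adjusted over the list alone. Enzymes of cholesterol synthesis were lower as a group, with 0 of 20 above 0, a median of -0.68 and Mvk at -1.25 ± 0.38 and Fdft1 at -0.92 ± 0.27; 0 passed over all genes and 2 were lower adjusted over the list alone. For the cholesterol synthesis list the adjusted p was 3.56e-09 (adjusted p = 0.301 with an estimated correlation). Extracellular matrix and mesenchymal genes were higher as a group, with 27 of 30 above 0, a median of 0.62 and fibronectin, Fn1, at 3.55 ± 0.92 and Ccn2 at 2.71 ± 0.74; 0 passed over all genes and 6 were higher adjusted over the list alone. For the extracellular matrix list the adjusted p was 3.56e-09 (adjusted p = 0.197 with an estimated correlation). TGF-beta and BMP genes were higher as a group, with a median of 0.35; Smad7 rose and 20 of 21 did not pass over all genes, while 2 were higher adjusted over the list alone. For the TGF-beta and BMP list the adjusted p was 0.00150 (adjusted p = 0.197 with an estimated correlation). With the preset correlation these 4 lists kept their calls whichever array was left out, and 7 further lists passed but lost the call when at least 1 array was left out. The leave-outs do not bear on the estimated correlation. With fry the unadjusted p were 0.0169 for G1/S, 0.0935 for cholesterol synthesis, 0.0134 for the extracellular matrix and 0.00312 for the TGF-beta and BMP list. Among the latter, the pericyte and smooth muscle list (7 of 8 above 0, median 0.70) and the astrocyte list (median 0.38) were higher, with adjusted p of 0.00858 and 0.0166 (0.219 for each with an estimated correlation). The oligodendrocyte progenitor list, at a median of -0.55, lost it without 3447 SP array 2 (adjusted p = 0.0934). For the oligodendrocyte progenitor list the adjusted p was 0.000568 (adjusted p = 0.219 with an estimated correlation).

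In neurospheres the same comparison asked what distinguishes dye-excluding cells of untransformed cultures. Atf3, an immediate early and stress-response transcription factor, was higher in SP cells, at 1154 ± 140 against 240 ± 16.1 (SD, n = 3), a log2 fold change of 2.24 ± 0.31 and an adjusted p of 0.0217. Slc1a1, a glutamate transporter, was lower, at 368 ± 145 against 1265 ± 201, a log2 fold change of -1.75 ± 0.26 and an adjusted p of 0.0259. The arrays of the groups did not overlap for either gene. Abcg2 was at 5970 ± 643 in SP and 3848 ± 468 in non-SP cells and did not pass, at 0.57 ± 0.23 with an adjusted p of 1.00. The SP arrays of Abcg2 all lay above its non-SP arrays, with log2 values of 12.33 to 12.63 against 11.80 to 12.09. In limma 1 gene was higher and 1 lower, and 428 had an unadjusted p under 0.05. In 7.60% of genes the groups did not overlap, against 10% by chance with unpaired arrays and 3.96% in a simulation with arrays paired by number as observed, run after the data were seen. With neurosphere arrays paired, a setting chosen after the data were seen, 4 genes were higher and 3 lower. Among them were Ccn1 at 1.68 ± 0.28, Emp1 at 1.19 ± 0.18, Lhfpl3 at -2.01 ± 0.30 and Atcay at -1.30 ± 0.20. Abcg2 did not pass with this pairing either. With a block in both origins, 14 passed. The Atf3 call was lost when any of the 6 neurosphere arrays or any of the 3 arrays of the 3447 non-SP was left out (adjusted p = 0.0507 to 0.0937). The Slc1a1 call was lost without any of these except neurosphere SP array 3, and without 4346 SP array 2 (adjusted p = 0.0546 to 0.139). With arrays centred on their medians, the compared groups alone or no trend of spread, neither gene passed (adjusted p = 0.0795, 0.106 and 0.0568 for Atf3 and 0.0795, 1.00 and 0.104 for Slc1a1). With the mean of its probe sets Slc1a1 did not pass either (adjusted p = 0.138). Among the leave-outs, the count was 0 without any of the 3447 non-SP arrays, neurosphere SP array 1 or 2 or non-SP array 2 or 3. It was 1 without 4346 SP array 2, neurosphere SP array 3 or non-SP array 1, and 3 without 3447 SP array 2 or 3.

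Among the gene lists in neurospheres, immediate early and dissociation stress genes were higher in SP cells as a group, with 27 of 29 above 0 and a median log2 of 0.40. For the immediate early list the adjusted p was 3.77e-11 (adjusted p = 0.0953 with an estimated correlation). Atf3 rose, while Hspa1b, a heat shock protein, at 1.30 ± 0.37 and Klf6 at 0.51 ± 0.15 did not pass over all genes, and 4 were higher adjusted over the list alone. Oligodendrocyte progenitor genes were lower as a group, with 1 of 15 above 0 and a median of -0.49. For the oligodendrocyte progenitor list the adjusted p was 8.11e-08 (adjusted p = 0.0953 with an estimated correlation). Lhfpl3 at -2.01 ± 0.52, the receptor Gpr17 at -1.50 ± 0.42 and the matrix protein Tnr at -1.28 ± 0.35 did not pass over all genes, and 3 members were lower adjusted over the list alone. NRF2 and detoxification genes were higher as a group, with 18 of 21 above 0 and a median of 0.20, and 0 members passed over all genes or adjusted over the list alone. For the NRF2 list the adjusted p was 0.00219 (adjusted p = 0.0953 with an estimated correlation). These 3 lists kept their calls whichever array was left out, and 11 further lists that passed lost the call when at least 1 array was left out. Among the latter were other cell type lists. Astrocyte genes (18 of 20 above 0, median 0.51) and ependymal genes (6 of 6 above 0, median 0.90) were higher and neuron genes (median -0.12) lower. Their adjusted p were 0.0101, 0.00416 and 0.00228 (0.239, 0.0953 and 0.239 with an estimated correlation).

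Whether the SP effect differed between tumour line and neurospheres was tested as an interaction, which called 0 genes in limma, while 266 had an unadjusted p under 0.05. The 5 genes with the smallest p did not pass, each with an adjusted p of 0.999. They were the kinase gene Stk32b (2.99 ± 0.66), the chromatin remodelling subunit Smarcb1 (-1.97 ± 0.46), Slc1a1 (1.46 ± 0.36), the guidance molecule Ntn4 (1.95 ± 0.50) and Palm2 (1.63 ± 0.42). Other probe sets moved the same way by less, at -0.07 for Smarcb1, 0.93 for Slc1a1 and 0.19 for Palm2. For Abcg2 the difference of effects was 0.33 ± 0.32, which did not pass (adjusted p = 0.999). The count was 1 without 4346 SP array 1 and 2 with a replicate block in both origins. G2/M genes had a lower SP effect in line 3447 than in neurospheres, with 0 of 34 members above 0 and a median of -0.69, and kept that call whichever array was left out; Aurka, a mitotic kinase, was at -1.09 ± 0.47 and did not pass. For the G2/M list the adjusted p was 8.48e-11 (adjusted p = 0.693 with an estimated correlation). Across all genes, the log2 SP effects of the tumour line and of neurospheres had a Pearson r of 0.315, where genes are not independent replicates.

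The SP effect averaged over line 3447 and neurospheres asked for the mean effect of both origins, which an effect in 1 of them can carry. Smad7 (1.84 ± 0.22, adjusted p = 0.00518), Atf3 (1.63 ± 0.22, adjusted p = 0.00518) and the matrix protein Ccn1 (1.39 ± 0.20, adjusted p = 0.00961) were higher in SP cells. Ptger4, a prostaglandin E receptor, at 1.95 ± 0.32, the AP-1 transcription factor Fosl2 at 1.61 ± 0.29 and the noncoding gene Rab26os at 1.51 ± 0.27 were also higher, with adjusted p of 0.0431, 0.0451 and 0.0451. Slc1a1 (-1.03 ± 0.18), the synaptic protein Lrrtm1 (-1.74 ± 0.32) and the cytoskeletal Septin3 (-0.72 ± 0.14) were lower, with adjusted p of 0.0451, 0.0455 and 0.0473. The change of Slc1a1 came mostly from neurospheres, at -1.75 ± 0.26 there against -0.30 ± 0.26 in line 3447, where the arrays of the groups overlapped. In all, 17 genes were higher and 3 lower, and 1046 had an unadjusted p under 0.05; with arrays centred on their medians, 4 were higher and 4 lower. Abcg2 was at 0.73 ± 0.16 and did not pass (adjusted p = 0.114), nor with the block among neurospheres alone (adjusted p = 0.0515). It passed without 3447 SP array 2 (adjusted p = 0.0252), and with a replicate block in both origins (adjusted p = 0.0366), which the arrays of line 3447 do not support. The count was 95 (74 higher, 21 lower) with neurosphere arrays paired and 192 (143 higher, 49 lower) with a block in both origins.

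Leaving out 1 array took the averaged count down to 5, 6 and 4 without 3447 SP arrays 1, 2 and 3, and to 7, 4 and 5 without 3447 non-SP arrays 1, 2 and 3. It was 5 without 4346 SP array 2, 6, 4 and 9 without neurosphere SP arrays 1, 2 and 3, and 5 without neurosphere non-SP array 2. Smad7, Atf3 and Ccn1 kept their calls in each of these; Ccn1 lost it with arrays centred on their medians (adjusted p = 0.122) and with the mean of its probe sets (adjusted p = 0.0928). Each of Ptger4, Fosl2, Rab26os, Lrrtm1, Slc1a1 and Septin3 lost it in 11 or more of the 15 leave-outs, with adjusted p of 0.0515 to 0.137 there. By gene group, 13 lists passed with the preset correlation and 0 with the estimated one, and 10 of the 13 kept the call whichever array was left out. Of these 10, the extracellular matrix, immediate early, astrocyte, ependymal, TGF-beta and EGF receptor lists were higher, with medians of 0.49, 0.28, 0.50, 0.95, 0.21 and 0.13. Their adjusted p were 1.65e-08, 1.14e-06, 0.00180, 0.00545, 0.00308 and 0.00308. The ependymal list lost its call in 1 of the other processing alternatives (adjusted p = 0.318). The cholesterol synthesis list was lower, at a median of -0.46 (adjusted p = 1.65e-08). Progenitor genes of the oligodendrocyte lineage were lower, with 0 of 15 above 0 and a median of -0.41, 0 past the test over all genes and 4 lower adjusted over the list alone, Gpr17 being at -1.33 ± 0.29. For the oligodendrocyte progenitor list the adjusted p was 3.45e-08 (adjusted p = 0.09996 with an estimated correlation). G1/S genes were lower, with 0 of 30 above 0 and a median of -0.41, 0 past the test over all genes and 2 lower adjusted over the list alone. For the G1/S list the adjusted p was 1.92e-14 (adjusted p = 0.121 with an estimated correlation). NRF2 and detoxification genes were higher, at a median of 0.21, with 0 past the test over all genes and 2 higher adjusted over the list alone, the quinone reductase Nqo1 being at 0.95 ± 0.22. For the NRF2 list the adjusted p was 0.00254 (adjusted p = 0.09996 with an estimated correlation).

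**Figure D1:**
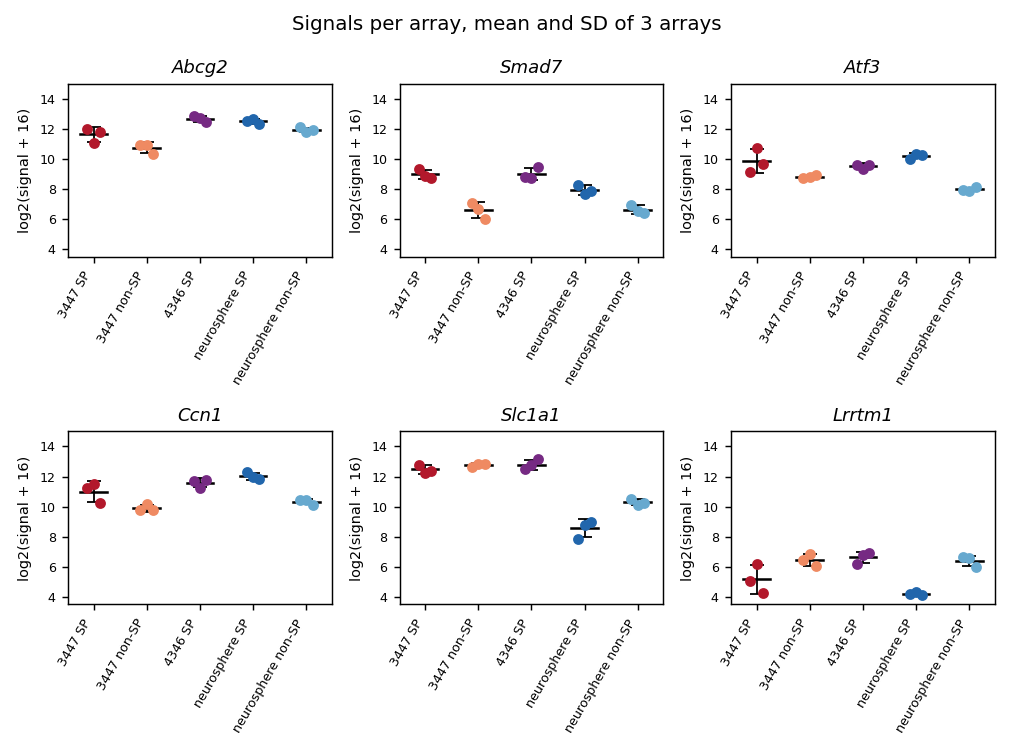
Signal of 6 genes on each array, as log2(signal + 16), in the 5 groups of 3 arrays; points are arrays, bars the mean and whiskers the SD. Smad7 lay higher in SP than in non-SP cells in line 3447, and Atf3 higher and Slc1a1 lower in SP cells of neurospheres.

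The SP of line 3447 against the SP of neurospheres asked how SP cells of this tumour line differ from untransformed ones. Mbp, myelin basic protein, was among the genes with the highest fold changes and had a signal of 8316 ± 1940 against 14.3 ± 8.98 (SD, n = 3), a log2 fold change of 8.22 ± 0.34 (adjusted p = 2.98e-10). Sox10, a transcription factor of that lineage, was at 3123 ± 504 against 1.29 ± 0.43, a log2 fold change of 7.49 ± 0.35. Both genes had almost no signal in the neurosphere SP, so the sizes of their changes depend on the added constant. Others of the highest were Hapln1, a link protein, at 8.23 ± 0.47 and the collagen Col2a1 at 8.10 ± 0.31. The proteoglycan Acan was at 8.06 ± 0.34, Fmod at 7.15 ± 0.45 and Col9a1 at 6.81 ± 0.40. Snai2, a transcription factor of neural crest and mesenchyme, was at 6.94 ± 0.30, and the export factor Nxf3 at 7.35 ± 0.59. The mouse EGF receptor gene, Egfr, was almost without signal in the tumour SP, at 25.2 ± 8.93 against 5016 ± 2230, a log2 fold change of -6.97 ± 0.44 (adjusted p = 1.72e-08). Also lower were the membrane proteins Mlc1, Slc4a4 and Gja1: Mlc1 was at -7.12 ± 0.43, Slc4a4 at -6.74 ± 0.44 and Gja1 at -5.80 ± 0.75. The glutamate receptor Grm5 was at -6.76 ± 0.31, the carbonic anhydrase Car2 at -6.12 ± 0.37 and Adgrl2 at -6.85 ± 0.44. Other probe sets moved the same way, several of them by less. They were at 0.75 to 4.02 for Hapln1, 3.17 to 4.69 for Sox10 and -6.15 to -0.46 for Egfr. For Mbp they ran from 1.68 to 8.04, and for Grm5 and Adgrl2 they stood at -6.45 and -6.42.

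Of the stem cell and transporter genes in that comparison, Nes was lower at 403 ± 73.6 against 1306 ± 158 (log2 -1.73 ± 0.24, adjusted p = 8.12e-05) and Prom1 lower at 20.5 ± 12.4 against 573 ± 622 (log2 -3.65 ± 0.71, adjusted p = 0.00168). Sox2 did not pass, at 6382 ± 823 against 6689 ± 500 (log2 0.03 ± 0.12, adjusted p = 0.909), nor did Abcb1b at -0.29 ± 0.33 (adjusted p = 0.588). Abcg2 was lower in the tumour SP, at 3219 ± 994 against 5970 ± 643 (log2 -0.87 ± 0.23, adjusted p = 0.0124), a call lost without 3447 SP array 2 (-0.59, adjusted p = 0.0627). In limma 1270 genes were higher and 1067 lower, of which 921 and 716 changed at least 2-fold; with arrays centred on their medians, 731 were higher and 842 lower, so the more frequent direction depends on the scaling. In this comparison 36.0% of genes had groups that did not overlap, against 10% by chance.

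By gene group, 12 of 21 listed genes of myelinating oligodendrocytes passed the filter on signal; 9 of the 12 rose, 0 fell and 3 did not pass, at a median log2 of 3.19; 10 were higher adjusted over the list alone. For the myelinating oligodendrocyte list the adjusted p was 1.74e-09 (adjusted p = 0.00406 with an estimated correlation). Besides Mbp, the higher genes included the gap junction protein Gjc3 at 4.91 ± 0.36, the tight junction protein Cldn11 at 4.45 ± 0.51 and Tspan2 at 2.99 ± 0.36. Among oligodendrocyte progenitor genes, 6 of 15 rose and 2 fell over all genes, and 8 and 2 adjusted over the list alone, at a median of 1.22; Pdgfra, the PDGF receptor of these cells, was up by 3.21 ± 0.52 and Cspg4 by 3.13 ± 0.39. For the oligodendrocyte progenitor list the adjusted p was 0.0234 (adjusted p = 0.535 with an estimated correlation). That call was lost without 3447 SP array 3 (adjusted p = 0.0874) and without 4346 SP array 3 (adjusted p = 0.0511). It was also lost in 2 other processing alternatives (adjusted p up to 0.152). Of 30 extracellular matrix and mesenchymal genes 14 rose and 5 fell over all genes, and 16 and 5 adjusted over the list alone, at a median of 1.44, with Mgp at 6.42 ± 0.57, Col1a1 at 3.85 ± 0.56 and Col6a1 at 3.30 ± 0.47. For the extracellular matrix list the adjusted p was 0.0146 (adjusted p = 0.535 with an estimated correlation). Of 20 astrocyte genes 10 fell and 1 rose over all genes, and 11 and 2 adjusted over the list alone, at a median of -1.33. For the astrocyte list the adjusted p was 0.00343 (adjusted p = 0.308 with an estimated correlation). Of 32 oxidative phosphorylation genes 5 fell and 0 rose, by either adjustment, at a median of -0.24, with the complex III subunit Uqcrc1 at -1.13 ± 0.24. For the oxidative phosphorylation list the adjusted p was 0.0129 (adjusted p = 0.535 with an estimated correlation). Neuron and neural stem genes passed as lists as well, but lost the call in 3 and 5 of the 15 leave-outs, with adjusted p up to 0.174 and 0.167 without neurosphere SP array 2. With an estimated correlation each had an adjusted p of 0.535.

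In the SP of line 4346 against the SP of neurospheres, the same genes led. Col2a1 (8.29 ± 0.31), Sox10 (8.24 ± 0.35), Mbp (8.201 ± 0.34), Acan (7.95 ± 0.34), Susd5 (7.73 ± 0.39), Hapln1 (7.61 ± 0.47), Col9a1 (7.35 ± 0.40), Fmod (7.21 ± 0.45) and Nxf3 (7.14 ± 0.59) were among the 10 highest in both lines, and Cnmd, chondromodulin, was at 7.32 ± 0.35. Mlc1 (-8.39 ± 0.43), Slc4a4 (-7.28 ± 0.44), Egfr (-7.20 ± 0.44), Grm5 (-6.78 ± 0.31) and Ccbe1 (-6.27 ± 0.40) were among the 10 lowest in both. Neural transcription factors Sox1 (-6.28 ± 0.42) and Rfx4 (-5.97 ± 0.36), the neuronal membrane protein Gpm6a (-7.75 ± 0.62), the neuropeptide receptor Adcyap1r1 (-5.10 ± 0.55) and Erdr1 (-7.19 ± 0.24) were the other genes among the 10 lowest. Nes (-1.67 ± 0.24, adjusted p = 0.000113) and Prom1 (-3.71 ± 0.71, adjusted p = 0.00123) were lower, and Abcg2, at 6621 ± 826 against 5970 ± 643 (log2 0.17 ± 0.23, adjusted p = 0.631), and Sox2 (-0.07 ± 0.12, adjusted p = 0.687) did not pass. In all 1663 genes were higher and 1228 lower, and 36.9% of genes had groups that did not overlap, against 10% by chance; with arrays centred on their medians, 1669 were higher and 545 lower.

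The lists moved in line 4346 as follows. Of 12 myelinating oligodendrocyte genes 11 rose and 0 fell, by either adjustment (11 higher adjusted over the list alone), at a median of 3.57, with Plekhb1 at 3.69 ± 0.40 and Fa2h, an enzyme of myelin lipids, at 3.45 ± 0.33. For the myelinating oligodendrocyte list the adjusted p was 4.97e-09 (adjusted p = 0.00494 with an estimated correlation). Extracellular matrix and mesenchymal genes rose in 16 of 30 cases and fell in 3, and in 17 and 3 adjusted over the list alone, at a median of 1.66, with Mmp2, a matrix protease, at 6.67 ± 0.40 and Mgp, matrix Gla protein, at 6.05 ± 0.57. For the extracellular matrix list the adjusted p was 3.85e-05 (adjusted p = 0.258 with an estimated correlation). Oligodendrocyte progenitor genes rose in 7 of 15 cases and fell in 1, and in 7 and 3 adjusted over the list alone, at a median of 1.70, with Cspg4 at 4.21 ± 0.39. For the oligodendrocyte progenitor list the adjusted p was 0.00321 (adjusted p = 0.340 with an estimated correlation). Neural stem and progenitor genes fell in 14 of 26 cases and rose in 1, the same counts adjusted over the list alone, at a median of -0.73, with Nr2e1 at -3.49 ± 0.48. For the neural stem and progenitor list the adjusted p was 3.85e-05 (adjusted p = 0.123 with an estimated correlation). Astrocyte genes fell in 7 of 20 cases and rose in 1, and in 11 and 2 adjusted over the list alone, at a median of -1.25, and S100b, which is also made by oligodendrocyte lineage cells, was up by 3.91 ± 0.58. For the astrocyte list the adjusted p was 0.00425 (adjusted p = 0.258 with an estimated correlation). Neuron genes fell in 9 of 21 cases and rose in 1, and in 10 and 1 adjusted over the list alone, at a median of -0.70, with Stmn3 at -4.72 ± 0.53. For the neuron list the adjusted p was 0.00307 (adjusted p = 0.258 with an estimated correlation). The oxidative phosphorylation list passed as well, at a median of -0.25. It lost the call without 4346 SP array 2 (adjusted p = 0.195) and in 1 other processing alternative (adjusted p = 0.313). For that list the adjusted p was 0.00425 (adjusted p = 0.529 with an estimated correlation).

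Both tumour lines were set against the same 3 neurosphere SP arrays, so their changes share chance values. Together 972 genes were higher and 662 lower in both lines, and 3 moved in opposite directions. Independent lists of these sizes would share 177 and 110. Simulated unchanged groups gave 0 shared calls. They had almost no calls at all, with means of 0 to 0.15 per line and direction, so that 0 sets no scale for the shared count. The log2 fold changes had a Pearson r of 0.835 across genes, against 0.5004 in the simulation, and a covariance of 0.940 against 0.0665, a difference of 0.874. They had the same sign in 77.0% of genes, against 66.7% simulated. The simulated groups share their controls as well, so the covariance above the simulation allows for shared controls with the spread of these arrays. With 3 controls no division into parts of at least 2 arrays was possible. How many of the shared calls come from the shared controls was not estimated. In the fit of both lines together, 1705 genes were higher and 1414 lower than in the neurosphere SP, and 1299 and 814 with arrays centred on their medians. With the added 16 the highest were Mbp (8.21 ± 0.29), Col2a1 (8.198 ± 0.27), Acan (8.01 ± 0.29), Hapln1 (7.92 ± 0.40), Sox10 (7.86 ± 0.30) and Susd5 (7.62 ± 0.34). Their signals in the neurosphere SP were near background, at means of 1.29 to 39.2, so their fold changes and order depend on the added constant. Among these 6, Sox10 was the highest with a constant of 1 (10.71) and Acan with 64 (7.05). Mlc1 (-7.75 ± 0.37), Egfr (-7.09 ± 0.38), Slc4a4 (-7.01 ± 0.38), Grm5 (-6.77 ± 0.26), Gpm6a (-6.68 ± 0.53) and Ccbe1 (-6.01 ± 0.34) led downward, and Abcg2 did not pass (-0.35 ± 0.20, adjusted p = 0.209). Myelinating oligodendrocyte genes rose in 11 of 12 cases, by either adjustment (11 adjusted over the list alone), at a median of 3.25. The filter on signal favours members that are bright in the tumour groups; over all 19 members with a probe set the median was 1.17, and without the filter the list still passed (adjusted p = 6.20e-07). For the myelinating oligodendrocyte list the adjusted p was 2.11e-09 (adjusted p = 0.00421 with an estimated correlation). The 6 other lists named for line 4346 passed here too, but not with an estimated correlation.

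**Figure D2:**
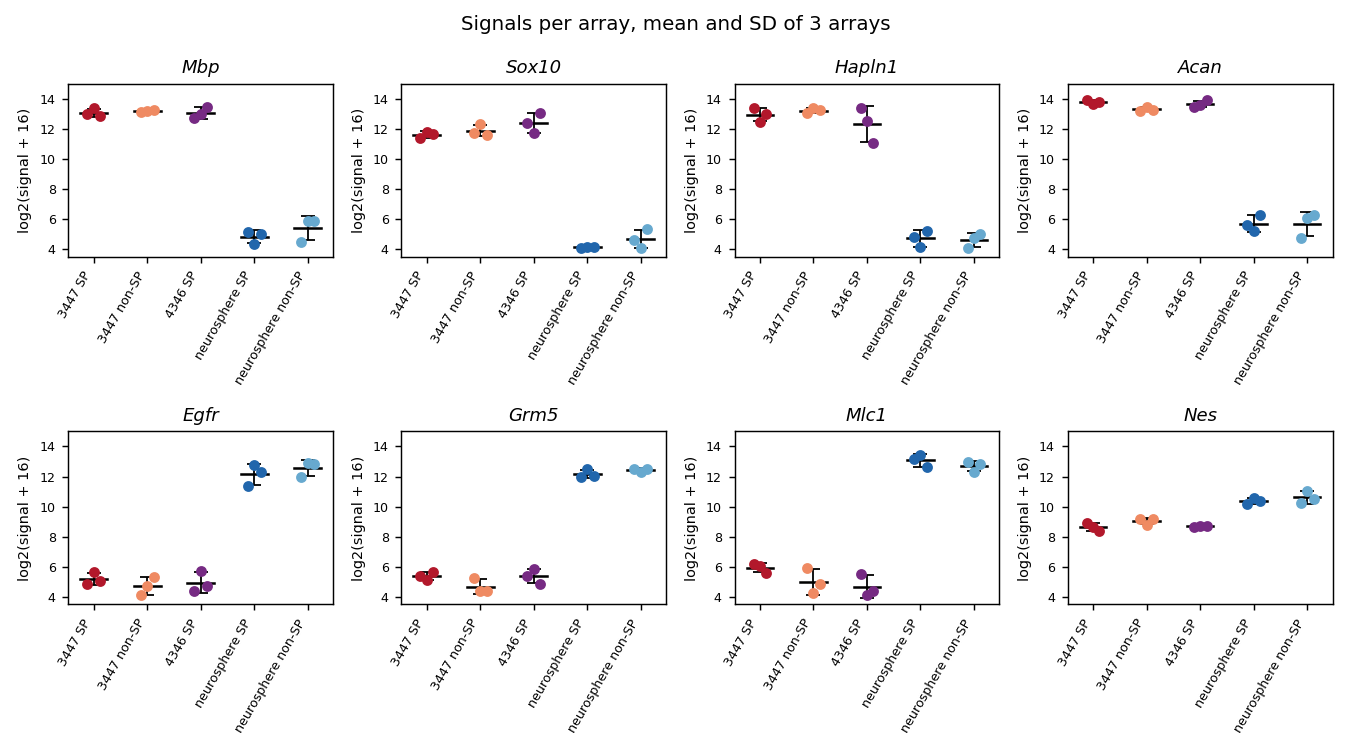
Signal of 8 genes on each array, as log2(signal + 16), in the 5 groups of 3 arrays; points are arrays, bars the mean and whiskers the SD. Mbp, Sox10, Hapln1 and Acan lay higher, and Egfr, Grm5, Mlc1 and Nes lower, in each tumour group than in the neurosphere groups.

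The non-SP cells of line 3447 against the non-SP cells of neurospheres asked whether the contrast of tumour and control extends to cells outside the side population. Col2a1 (8.61 ± 0.31), Hapln1 (8.59 ± 0.47), Mbp (7.74 ± 0.34), Acan (7.63 ± 0.34), Susd5 (7.26 ± 0.39) and Sox10 (7.20 ± 0.35) were the 6 highest. Adgrl2 (-8.36 ± 0.44), the cyclin gene Ccnd2 (-8.31 ± 0.69), Egfr (-7.82 ± 0.44), Grm5 (-7.74 ± 0.31), Mlc1 (-7.69 ± 0.43) and Slc4a4 (-7.33 ± 0.44) were the 6 lowest. Ccnd2 had a signal of 28.0 ± 26.1 in the tumour non-SP against 11928 ± 2359 in the neurosphere non-SP (SD, n = 3). Abcg2 was lower at 1717 ± 395 against 3848 ± 468 (log2 -1.20 ± 0.23, adjusted p = 0.00134), Nes lower at -1.56 ± 0.24 (adjusted p = 0.000219), and Prom1 lower at -2.62 ± 0.71 (adjusted p = 0.0154), a call lost without 3447 non-SP array 2 or 3 (adjusted p = 0.0584 and 0.0599) or neurosphere non-SP array 2 (adjusted p = 0.0837). In all 1332 genes were higher and 978 lower, and 38.8% of genes had groups that did not overlap, against 10% by chance; with arrays centred on their medians, 1199 were higher and 553 lower. This comparison shares no array with that of the 3447 SP and the neurosphere SP, but the neurosphere SP and non-SP arrays pair by number, so it is not independent of it. In both, 951 genes were higher and 688 lower, and 0 were opposite. The fold changes had a Pearson r of 0.900 across genes. Simulated unchanged groups with neurosphere arrays paired as observed, chosen after the data were seen, gave an r of 0.289 and 0 shared calls. They had almost no calls at all, so only the r sets a scale here.

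The lists called in the non-SP comparison were in part those of the SP comparison. The extracellular matrix list (median 0.60) and the oxidative phosphorylation list (median -0.07), called there, did not pass here (adjusted p = 0.218 for each). The G2/M list, called here, was at a median of 0.06 there (adjusted p = 0.959). Myelinating oligodendrocyte genes rose in 10 of 12 cases and 0 fell, and 11 were higher adjusted over the list alone, at a median of 3.43, with Gjc3 at 4.28 ± 0.36. For the myelinating oligodendrocyte list the adjusted p was 6.26e-10 (adjusted p = 0.00338 with an estimated correlation). Astrocyte genes fell in 8 of 20 cases and rose in 2, and in 9 and 2 adjusted over the list alone, at a median of -1.29, with the glutamate transporter Slc1a3 at -2.40 ± 0.25. For the astrocyte list the adjusted p was 0.00312 (adjusted p = 0.294 with an estimated correlation). Neuron genes fell in 7 of 21 cases and rose in 1, and in 11 and 3 adjusted over the list alone, at a median of -0.71, with the GABA-synthesising enzyme Gad1 at -3.53 ± 0.60. For the neuron list the adjusted p was 0.00264 (adjusted p = 0.303 with an estimated correlation). G2/M genes rose in 5 of 34 cases and 0 fell, and 4 were higher adjusted over the list alone, at a median of 0.69, with the cytokinesis gene Racgap1 at 1.55 ± 0.35. For the G2/M list the adjusted p was 0.00171 (adjusted p = 0.848 with an estimated correlation). Neural stem and oligodendrocyte progenitor genes passed as lists as well, but lost the call in 1 and 6 of the 15 leave-outs, with adjusted p up to 0.0752 without neurosphere non-SP array 2 and 0.0863 without neurosphere non-SP array 1. With an estimated correlation their adjusted p were 0.390 and 0.744.

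The SP of line 3447 against the SP of line 4346 asked how the tumour lines differ. Erdr1 (7.70 ± 0.24) and the neural transcription factors Sox1 (6.68 ± 0.42) and Zic1 (5.51 ± 0.93) were higher in line 3447, Sox1 with a signal of 2035 ± 564 against 3.03 ± 3.62 (SD, n = 3, adjusted p = 1.25e-07). The transcription elongation gene Ctr9 was at 4.87 ± 0.31, the imprinted gene Impact at 3.22 ± 0.28 and the neuronal microtubule gene Stmn3 at 3.16 ± 0.53. Other probe sets of these higher genes moved the same way by less. The 4 others of Ctr9 were at 0.34 to 1.12, and those of Erdr1, Zic1 and Stmn3 at 1.48, 1.63 and 1.37. That of Impact was at 3.02. The lysosomal protease Ctsz (-5.70 ± 0.34), Piwil4 (-5.41 ± 0.62), the collagen chaperone Serpinh1 (-5.04 ± 0.80), Adgrl2 (-4.91 ± 0.44), the co-chaperone Bag3 (-4.86 ± 0.38) and Ppic (-4.82 ± 0.35) were lower in line 3447. Abcg2 was lower in line 3447 as well, at 3219 ± 994 against 6621 ± 826 (log2 -1.04 ± 0.23, adjusted p = 0.0273), a call lost without 3447 SP array 2 or 3 (adjusted p = 0.104 and 0.0566) or 4346 SP array 1 or 2 (adjusted p = 0.0808 and 0.0531). In limma 55 genes were higher and 142 lower, with 19.6% of genes in groups that did not overlap against 10% by chance; with arrays centred on their medians, 23 were higher and 344 lower. Without 3447 SP arrays 1, 2 and 3 the count was 121, 114 and 107, and without 4346 SP arrays 2 and 3 it was 326 and 123. With both arrays of doubtful quality left out, chosen after the data were seen, 21 were higher and 56 lower, and Zic1, Stmn3 and Serpinh1 did not pass (adjusted p = 0.0699, 0.102 and 0.0699).

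Between the tumour lines, 3 of 26 neural stem and progenitor genes rose in line 3447 and 0 fell, and 4 were higher adjusted over the list alone, at a median of 0.12. For the neural stem and progenitor list the adjusted p was 0.00877 (adjusted p = 0.673 with an estimated correlation). The 3 higher genes were Sox1, Zic1 and Cd24a at 0.45 ± 0.08, the last of which turned to -0.06 (adjusted p = 0.898) with arrays centred on their medians. Of 30 extracellular matrix and mesenchymal genes 4 fell and 0 rose, and 6 were lower adjusted over the list alone, at a median of -0.57, with Mmp2 at -4.44 ± 0.40 and the protease inhibitor Timp1 at -3.26 ± 0.56. For the extracellular matrix list the adjusted p was 0.00878 (adjusted p = 0.673 with an estimated correlation). That list lost its call without 3447 SP array 2 (adjusted p = 0.0591) and without 4346 SP array 3 (adjusted p = 0.0881), the array with the raised 3' to 5' ratios. It also lost it in 2 other processing alternatives (adjusted p up to 0.280). Timp1 lost its call with both doubtful arrays left out (adjusted p = 0.0778). The hypoxia and glycolysis list passed as well, at a median of -0.29, and lost the call in 3 of the 15 leave-outs. For the hypoxia list the adjusted p was 0.0402 (adjusted p = 0.792 with an estimated correlation).

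**Figure D3:**
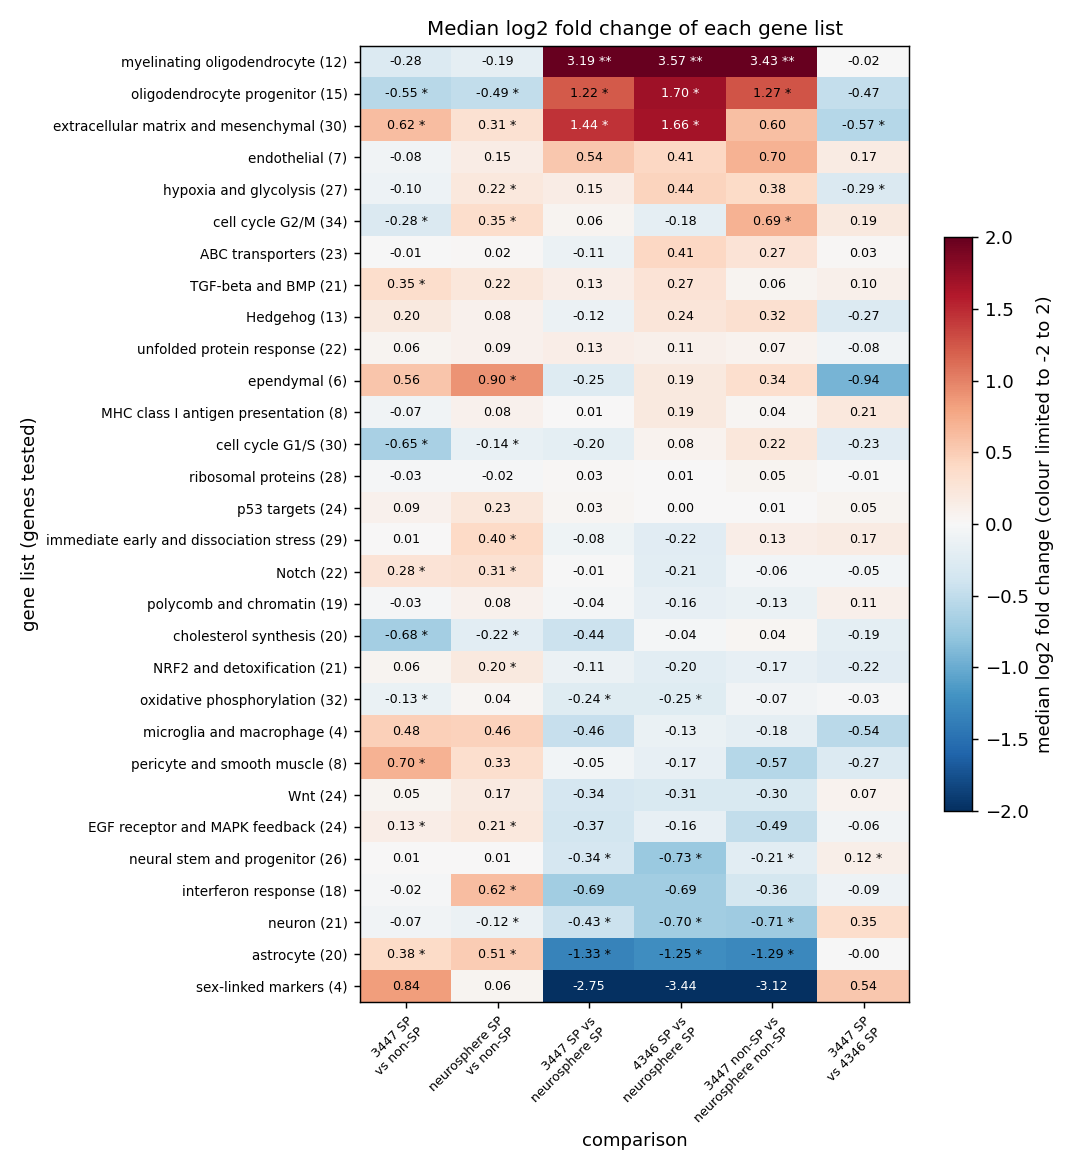
Median log2 fold change of each gene list in 6 comparisons, with the number of genes tested in parentheses; 1 asterisk marks an adjusted p under 0.05 with the preset correlation and a double asterisk one that also passed with the estimated correlation. Myelinating oligodendrocyte genes carried the double mark in the tumour against neurosphere comparisons shown, with medians of 3.19, 3.57 and 3.43.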

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

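The interaction test and the counts of other divisions of the arrays were fixed before the results were seen; only the division by neurosphere pairs was chosen afterwards. The difference between the SP effect of line 3447 and that of neurospheres flagged 7 gene lists, each because the interaction itself passed with the preset correlation. None of the 7 passed with an estimated correlation, and no single gene passed. G2/M genes had a median difference of -0.69 (adjusted p = 8.48e-11; adjusted p = 0.693 with an estimated correlation), and this call stayed whichever array was left out. In line 3447 SP cells their median was -0.28, a call that was lost and reversed without 3447 SP array 2 (adjusted p = 0.479). In neurosphere SP cells it was 0.35, a call lost in 2 of the 15 leave-outs (adjusted p up to 0.350). Neither passed with an estimated correlation (adjusted p = 0.588 and 0.557), so the direction within each origin is not settled. G1/S genes had a median difference of -0.46 (adjusted p = 8.58e-07; adjusted p = 0.693 with an estimated correlation), lost without 3447 SP array 2 (adjusted p = 0.0815). Immediate early and dissociation stress genes had a median difference of -0.31 (adjusted p = 0.000618; adjusted p = 0.671 with an estimated correlation), lost without 3447 SP array 1 (adjusted p = 0.0640).

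Cholesterol synthesis genes had a median difference of -0.37 (adjusted p = 0.00323; adjusted p = 0.861 with an estimated correlation), lost without any of 4 arrays (adjusted p up to 0.766, without neurosphere SP array 3). Hypoxia and glycolysis genes had a median difference of -0.33 (adjusted p = 0.00383; adjusted p = 0.861 with an estimated correlation), lost without any of 5 arrays (adjusted p up to 0.723, without neurosphere SP array 3). Extracellular matrix and mesenchymal genes had a median difference of 0.33 (adjusted p = 0.00967; adjusted p = 0.693 with an estimated correlation), lost without any of 4 arrays (adjusted p up to 0.276, without 3447 SP array 1). Oxidative phosphorylation genes had a median difference of -0.17 (adjusted p = 0.0196; adjusted p = 0.693 with an estimated correlation), lost without any of 5 arrays (adjusted p up to 0.331, without 3447 non-SP array 2). No biological explanation of these differences was tested.

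Whether other divisions of the same arrays give as many genes was counted with the compared groups alone in the fit. For 6 comparisons of 3 arrays with 3, 10 divisions are too few for a share under 0.05. For SP against non-SP in line 3447 the real division gave 18 genes and the highest other 0, with 1 of 10 divisions as large. In neurospheres it gave 0 and the highest other 2, with 10 of 10 as large. It gave 2192 for the 3447 SP and 1764 for the 4346 SP against the neurosphere SP, 116 between the tumour SP groups and 2456 for the non-SP groups, each with a highest other of 0 and 1 of 10 as large. For both tumour lines against the neurosphere SP, 1 of 84 divisions was as large, with 2270 genes against a highest other of 36. The 6 tumour arrays come from only 2 lines with 3 replicates each. The count therefore measures spread among arrays and not among tumours. For the interaction 10 of 100 divisions were as large, with 1 gene against a highest other of 63. For the averaged SP effect 3 of 100 were as large, with 13 genes against a highest other of 26. The divisions with 63 and 26 genes each parted 1 of the 3 neurosphere pairs and kept the others together. Both kept the 3447 SP apart from the 3447 non-SP, as did a division of the averaged effect with 16 genes. Their counts thus hold the real SP effect of that line and do not measure chance alone. Among the 42 divisions that part all 3 neurosphere pairs, the averaged effect had a highest other count of 0. Among the 37 for the interaction it was 13. That division joined the 3447 non-SP with the neurosphere SP, which is the averaged SP effect with its sign changed, so it is no measure of chance either.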

How the results depend on the processing

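The removal of the pair of doubtful arrays and the replicate block among neurospheres alone were chosen after the data were seen; the other alternatives were fixed earlier. Of 1170 results for named genes, 3 reversed under any of 29 alternatives, and of 75 list calls 3 reversed under any of 27. Between 1081 and 1162 of the 1170 gene results kept their side of the threshold without a reversal under each alternative that covered them all. A reversal of a gene was counted only where the main or the alternative value passed. Results that passed in neither setting counted as unchanged whatever their sign, which covers most results of the comparisons with few calls. The cause was not tested for any change below, except where fewer arrays or a stricter threshold is itself the cause.

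For SP against non-SP in line 3447, 1 gene changed. The count was 0 with arrays centred on their medians, without a filter, with the mean of a gene's probe sets and at an adjusted p under 0.01. It was 18 with the compared groups alone, 50 with array weights, 66 with a replicate block and 2 without the doubtful arrays. Equal numbers did not pair the 3447 arrays (correlations of -0.225, -0.249 and -0.120), so the block by equal numbers has no basis in the data there. In neurospheres, where 2 genes changed, the count was 0 with arrays centred on their medians, with the compared groups alone, without the trend of spread and at an adjusted p under 0.01. It was 1 with the mean of probe sets, 14 with a replicate block and 7 with the block among neurospheres alone. The interaction went from 0 to 1 with the compared groups alone and to 2 with a replicate block. The averaged effect, with 20 genes, gave 8 without normalization, 8 with arrays centred on their medians, 11 without a filter, 12 with the mean of probe sets and 6 with probe sets tested singly. It gave 13 with the compared groups alone, 4 without the trend, 192 with a replicate block, 95 with the block among neurospheres alone and 4 at an adjusted p under 0.01.

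Between the tumour lines, 197 genes became 125 with an added constant of 1, 367 with arrays centred on their medians, 316 with probe sets tested singly, 116 with the compared groups alone, 77 without the doubtful arrays and 74 at an adjusted p under 0.01. Counts with probe sets tested singly, here and above, are of probe sets and not of genes, and a gene can have several. Probe sets tested singly gave 3987 for the 3447 SP, 5210 for the 4346 SP and 5552 for both against the neurosphere SP, and 3981 for the non-SP groups. An adjusted p under 0.01 gave 1278, 1571, 1811 and 1304 in the same order. The 4346 SP comparison gave 1764 with the compared groups alone, and both lines 1844 at a change of at least 2-fold. The overlap of the lines was 1068 with arrays centred on their medians and 2772 with probe sets tested singly. Of 75 list calls, 4 stayed with an estimated correlation.

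Centring arrays on their medians moved the median log2 fold change of all genes by -0.29 for SP against non-SP in line 3447, -0.31 for the interaction and -0.14 for the averaged effect. It moved it by -0.15 for the 3447 SP and 0.18 for the 4346 SP against the neurosphere SP, -0.34 between the tumour lines and 0.14 for the non-SP groups.

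Leaving out 1 array at a time gave 0 to 4 genes for line 3447, 0 to 3 for neurospheres, 0 to 1 for the interaction and 4 to 28 for the averaged effect. The ranges were 1693 to 2785 for the 3447 SP, 2239 to 2974 for the 4346 SP and 2260 to 3248 for both lines against the neurosphere SP. They were 107 to 326 between the tumour lines, 1628 to 2706 for the non-SP groups, 1259 to 1703 for the overlap and 65 to 88 for the list calls. Of the list calls 40 stayed in each leave-out and 35 were lost in at least 1. Reversed were G2/M in line 3447 (adjusted p from 1.19e-07 to 0.479), and in neurospheres cholesterol synthesis (4.53e-08 to 0.840) and hypoxia (3.86e-08 to 0.987).

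Single genes reversed were Abcc5 in the 4346 SP comparison with the mean of its probe sets (0.0535), Atp5a1 in the non-SP comparison with arrays centred on their medians (0.0318) and Cd24a between the tumour lines with arrays centred on their medians (-0.0637). Signals near background limit the fold changes of dim genes.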

Other observations

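Among the patterns weighed here, the tests of late myelin genes and of gene clusters on chromosomes were written before their results were seen, and the others afterwards. The test of gene clusters covered only chromosomes 8, 12, 15 and 19. These had the largest shifts in these data, so that choice was not independent of the shifts. Single genes of the EGF receptor family and its regulators changed in the tumour SP cells, while most of their list did not pass. Against the neurosphere SP, both lines together had Erbb3, the neuregulin receptor of the oligodendrocyte lineage, at a log2 of 6.70 ± 0.28 (adjusted p = 1.10e-10) and the ligand Tgfa at 1.94 ± 0.25. Lrig1, a feedback inhibitor of the receptor, was at -3.29 ± 0.29 (adjusted p = 5.68e-07). The list of EGF receptor and MAPK feedback genes did not shift as a whole, with 3 of 24 higher, 5 lower and an adjusted p of 0.314; adjusted over the list alone the counts were 3 and 5. Of 24 Wnt genes 5 rose and 8 fell, and 6 and 9 adjusted over the list alone, with the secreted inhibitors Dkk3 at 6.57 ± 0.31 and Wif1 at 2.94 ± 0.40 and the ligands Wnt7a at -3.89 ± 0.49 and Wnt5a at -2.65 ± 0.31.

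Among 24 p53 target genes 2 rose and 3 fell, the same counts adjusted over the list alone, at a median of -0.08 (adjusted p = 0.733). Phlda3 was at 2.83 ± 0.29 and the cell cycle inhibitor Cdkn1a at 2.498 ± 0.32. Of 23 ABC transporters 5 rose and 2 fell, the same counts adjusted over the list alone, with the cholesterol exporter Abcg1 at 2.65 ± 0.49 and Abca1 at -2.24 ± 0.32.

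In both tumour lines together, 11 of the 12 tested genes of the myelinating oligodendrocyte list, of 21 listed, were higher than in the neurosphere SP and 0 lower. Of 30 extracellular matrix genes 15 were higher and 5 lower. Mature oligodendrocytes of the host carried into the cultures would bring their late myelin genes, but the 6 late genes Mog, Mobp, Mag, Opalin, Ermn and Aspa had a median log2 difference of -0.36. Their mean signals in the tumour SP were 2.78 to 27.7. In the neurosphere SP they were dim as well, at 6.13 for Mog and 52.9 for Aspa. Genes this near background limit what the test can decide, and a small share of such cells cannot be excluded. Host microglia and endothelial cells could not be decided on. The larger of their list medians, over all members with a probe set, was 0.0489, but these genes lay near background in the tumour SP, with median signals of 17.6 and 23.6. Among the 7 endothelial genes tested, 2 rose and 1 fell, and the list did not pass (adjusted p = 0.566). Mesenchymal or fibroblast-like host cells were not tested and stay open. The extracellular matrix list had a median of 1.12 (adjusted p = 0.000870; adjusted p = 0.380 with an estimated correlation). Mbp had a mean signal of 8565 against 14.3, Bcas1 of 7883 against 452 and Enpp6 of 1053 against 16.5. An early oligodendrocyte lineage state of the tumour cells stays open and was not tested separately.

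Xist and the Y-linked genes Kdm5d, Eif2s3y and Uty were low in the tumour arrays. Neurosphere arrays differed among themselves. Arrays 3 had Xist signals of 7628 (SP) and 5817 (non-SP). The Kdm5d signal there was 12.2 and 4.60, against 673 to 731 on neurosphere arrays 1 and 2. A loss of X-linked signal as a whole is argued against, since 407 X-linked genes had a median log2 difference of 0.27. Xist expressed as in the neurospheres that have it is argued against too, since the highest tumour array reached 1.74% of their lowest. For Y-linked genes expressed as in the neurospheres that have them, the lines were tested separately. In line 4346 the highest array reached 2.02% of the lowest neurosphere array with such signal, which argues against it. In line 3447 the highest array reached 12.4%, between the bounds set, which leaves it undecided. That value came from the array of doubtful quality, and the highest of the 5 other arrays reached 4.36%. A retained Y chromosome with low expression cannot be excluded in either line. The sum of 3 genes was chosen after a single gene had been seen.

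Genes of several chromosomes were shifted together in both tumour lines against the neurosphere SP, relative to the other autosomes. Chromosomes 15 and 8 had medians of 0.56 and 0.49, and chromosomes 12 and 19 of -0.43 and -0.40, each in the same direction in 9 of 9 tumour arrays. These arrays are replicates of 2 lines and not 9 tumours. On these 4 chromosomes the neurosphere arrays lay between -0.11 and 0.06. Values per array are differences from the mean of the 3 neurosphere SP arrays, so these arrays lie near 0 by construction. Their range is thus no independent check. Elsewhere the neurosphere arrays were not free of shifts. Those numbered 2 were at 0.23 (SP) and 0.44 (non-SP) on chromosome 10, against -0.12 to -0.09 on the other neurosphere arrays. A few genes or a gene cluster as the source are argued against, since the smallest move of any quartile or part of the 4 chromosomes was 0.36, and so is a bias with expression level, at a distance of 0 percent from the end of the distribution of 10000 matched lists. Chromosome 1, shifted by only -0.09, also lay at the end of its matched lists, so that distance says little about size. The shifts may reflect changed chromosome numbers, for which 3 copies in place of 2 would give 0.585, 3 in place of 4 would give -0.415 and 1 in place of 2 would give -1. The lowered chromosomes lay far from the last of these values. No DNA was measured. Between the lines, chromosome 13 was higher in line 3447 by 0.41 and chromosome 5 was at -0.25.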
